A study of Mus musculus with 12 samples.

How the data were processed

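Liver RNA of female mice aged 8 to 12 weeks was hybridized to 12 single-colour Affymetrix arrays. The mice, floxed for Yap1, received AAV8-TBG-Cre (KO) or AAV8-TBG-GFP (WT), and 10 days later TCPOBOP at 3 mg/kg by gavage, with day 0 meaning no TCPOBOP. Per the titles, the arrays are 2 WT and 2 KO at day 0, 1 pool of each genotype at day 1 and 3 of each at day 2. The deposited values are MAS5 signal intensities made by the authors, per the submitters' processing notes, with no version given; each array was scaled to the same target, since the mean of the values between the 2nd and 98th percentiles is 500 on all arrays to within rounding. An aligner and a genome build are not given in the sources used here and do not apply to arrays. No depth per sample exists for arrays, whose number limits the precision.

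The intensities were used as deposited, as log2 of the value plus 16, without another normalization. Probe sets were joined to genes through the platform's annotation: 34945 name 1 gene, 932 several and 9160 none, and 64 are controls, and only those with 1 gene were tested. A probe set was kept when above its own array's median on at least 2 of the 12 arrays, and each gene was represented by its kept probe set with the highest mean log2 value, which left 14102 of 18193 genes. Probes of near-identical family members (Cyp2b, Cyp2c, Cyp3a, Gstm, Hspa1a and Hspa1b, Orm, Mt, Rdh) may read more than 1 gene. Ccnb1 has no probe set of its own and is not analysed here. Genomic positions are not used here.

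Genes were tested with limma 3.58.1 in R 4.3.3 by 1 fit of 6 group means to all 12 arrays (eBayes with trend and robust, 6 residual degrees of freedom). Day 2 was compared with day 0 in each genotype, KO with WT at day 2 and at day 0, and the change in KO with the change in WT. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and calls at an adjusted p under 0.05. The 32 fixed gene lists were tested with camera (preset correlation 0.01) and adjusted over the lists within a comparison, with camera's estimated correlation beside it; list calls are those of the preset correlation. Some genes stand in more than 1 list, such as Gstm1, Abcc3 and Abcc4 among phase II and NRF2 target genes. A count adjusted over the list alone adjusts the members' p values within that list. The day 1 arrays were not tested: list medians were ranked among 10000 random lists of the same size drawn from 20 bins of mean signal. Yap1 was also tested by exact permutation of genotype within days. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

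The groups, comparisons, tests, lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule names a panel (Yap1, Ccn1, Ccn2, Nr1i3, Cyp2b10, Cyp2c55, Cyp3a11, Gadd45b, Myc, Ccnd1, Ccna2, Cdk1, Mki67, Top2a, Foxm1, Cdkn1a). It adds the 10 largest called rises and falls of each comparison whose arrays do not overlap, up to 4 called members of each list, and at day 1 the 5 highest and 5 lowest genes shared by the genotypes. The genes in the text are a subset chosen for length after the values were seen. In WT, in KO and between the genotypes at day 2 it mostly leaves out genes whose call was lost without 1 array (5 of 52, 3 of 42 and 4 of 28 called genes given), but at day 0 and for the difference most are such genes (8 of 9 and 9 of 15).

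The lists are: CAR target and phase I drug metabolism; phase II conjugation and drug transporters; G1/S regulators; DNA replication; G2/M and mitosis; CDK inhibitors; p53, YAP/TAZ and NRF2 targets; Hippo components; mitogens; ribosome biogenesis; bile acids; gluconeogenesis and glycolysis; lipogenesis; cholesterol synthesis; fatty acid oxidation; hepatocyte identity; pericentral; periportal; acute phase; interferon-stimulated; unfolded protein response; immediate early and stress; circadian clock; and markers of Kupffer, endothelial, stellate, cholangiocyte, lymphocyte, neutrophil and erythroid cells. Lists needed at least 3 measured genes.

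Alternatives were quantile normalization, centring on the median, no pseudocount or 64, no filter or a stricter one, averaging or testing every probe set, eBayes without trend and robust, only the arrays compared, array weights, the replicate number as a block, other thresholds, an estimated correlation, and leaving out each replicate. Leaving out a day 0 array leaves 1 in its group, which is assumed to vary like the other groups. Cyclic loess normalization, and the alternatives for lists other than CAR target, DNA replication, G1/S, G2/M and YAP/TAZ target genes, were added after the values were seen. The fit was tested on simulated data of 14102 genes, with genes simulated independently. Of 100 genes changed 2-fold it recovered 35 at day 0, 47 in WT, 33 in KO, 38 between the genotypes at day 2 and 13 for the difference between responses. Of 100 changed 4-fold it recovered 76, 72, 85, 87 and 52, with 3.3% to 4.8% of calls false. Genes given a smaller shift as a list were not counted as false. The simulated arrays had normal noise and no difference in signal range, and few genes changed. The false share therefore does not cover the differences in range between the day 2 arrays described below.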

Results

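Gene expression was measured in mouse liver on 12 single-colour oligonucleotide arrays. The mice carried floxed alleles of Yap1, the gene for YAP, the transcriptional co-activator at the end of the Hippo growth control pathway. A liver-directed virus with Cre under the hepatocyte promoter TBG made the knockouts (KO), and a virus with GFP made the wild-type controls (WT). TCPOBOP, an agonist of the nuclear receptor CAR and a mitogen for hepatocytes, was given 10 days later at 3 mg/kg. Each genotype has 2 arrays at day 0, before TCPOBOP, 1 array of pooled RNA at day 1 and 3 arrays at day 2. The series asks whether hepatocyte YAP is needed for proliferation driven by CAR and for the induction of drug metabolism genes.

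Signals are MAS5 intensities, and the median of an array lay between 231.6 and 277 units. The number of arrays limits the precision. By the highest signals and the spiked controls, the KO day 2 arrays had a narrower range than the others and the WT day 2 arrays a wider one. By the mean log2 signal of the 200 most abundant genes, KO day 0 replicate 1 (14.764) lay above WT day 2 replicates 1 and 2 (14.706 and 14.597). The highest signals were 48217 to 67457 on KO day 2, 103216 to 116918 on WT day 2, and 71165 to 102372 on the 4 day 0 arrays. The spiked control transcript cre, added in the laboratory and not made by the liver, read 14114 to 17594 on KO day 2, 36037 to 38554 on WT day 2 and 22004 to 32153 at day 0. Between the genotypes at day 2, the median log2 difference (KO minus WT) ran from 0.21 for the 2021 genes with mean log2 signals under 8 to -0.41 for the 152 genes over 14. From day 0 to day 2 the median change of the genes over 14 was 0.16 in WT and -0.42 in KO. The deposited changes of abundant transcripts in WT and KO are thus not directly comparable. Differences of abundant transcripts between KO and WT at day 2 are therefore given with their value after quantile normalization, which sets all arrays to 1 distribution.

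**Figure D1:**
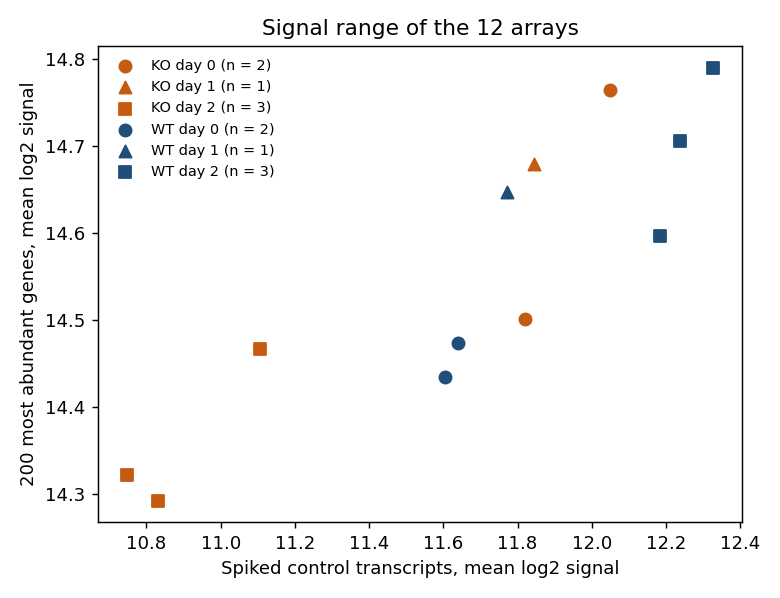
Mean log2 signal of the spiked control transcripts (horizontal axis) against the mean log2 signal of the 200 most abundant genes (vertical axis), 1 point per array, coloured by genotype and shaped by day. The 3 KO day 2 arrays have spiked controls between 10.75 and 11.11, and the 3 WT day 2 arrays between 12.18 and 12.33.

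Yap1 itself, by the brighter of its 2 probe sets, was lower on every KO array than on any WT array. This probe set read 1234 and 1293 in WT at day 0, 999.2 at day 1, and 1239.9, 1059.6 and 1306 at day 2. In KO it read 631.5 and 595.7 at day 0, 449.6 at day 1, and 571.5, 539.0 and 796.7 at day 2. The dimmer probe set overlapped between the genotypes, with 57.8 to 125.7 on the KO arrays and 23.1 (day 1 pool) to 389.3 in WT. For the brighter one, over all 12 arrays the KO minus WT difference was -0.99 on the log2 scale, with an exact permutation p of 0.00833 (two-sided, labels permuted within days), the smallest that the 240 arrangements can give. The limma test called it at day 2 (-0.92 ± 0.17, adjusted p 0.00844) but not at day 0 (-1.02 ± 0.20, adjusted p 0.0914). Whether the probes lie in the deleted part of the gene is not known here, and liver cells other than hepatocytes keep Yap1.

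In WT livers, phase II, G2/M and DNA replication genes were higher 2 days after TCPOBOP than before it, with YAP present. No group without TCPOBOP was sampled after day 0. Effects of the drug can therefore not be told apart from those of gavage, elapsed time or harvest conditions. Cyp2b10, the classical target of CAR, rose 30.7-fold (log2 4.94 ± 0.11), from 1583 and 1719 to signals between 47982 and 54064. Cdk1, the kinase that drives entry into mitosis, rose 23.4-fold (4.55 ± 0.27). Ppara, the receptor that controls fatty acid oxidation, fell 4.05-fold (-2.02 ± 0.21). No fold is given for a gene with a signal under 64 on an array of the lower group, since the 16 units added before taking logs shape it. In this and the other tested comparisons, ± gives the standard error from limma, with n = 2 arrays per genotype at day 0 and n = 3 at day 2.

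Of the CAR target and phase I drug metabolism genes, 18 of 26 measured rose and 4 fell, and adjusted over the list alone the counts were the same, 18 and 4. Cyp2c55 rose 57.2-fold (5.84 ± 0.17), the carboxylesterase Ces2a 16.4-fold (4.04 ± 0.15), Cyp3a44 5.16-fold (2.37 ± 0.30) and Cyp3a11 1.95-fold (0.97 ± 0.14, and 0.45 after quantile normalization). The list passed the camera test (adjusted p 3.52e-13), and its adjusted p was 0.0594 with an estimated correlation. Phase II conjugation and drug transporter genes rose in 24 of 31 and fell in 3 (25 and 3 adjusted over the list alone; adjusted p 9.8e-22, and 0.000901 with an estimated correlation). Among them were the estrogen sulfotransferase Sult1e1 (5.48 ± 0.41), the glutathione transferases Gstm3 (15.1-fold, 3.91 ± 0.18) and Gstm2 (2.88 ± 0.17), and the exporter Abcc4 (2.41 ± 0.21). NRF2 target genes, which answer to oxidative stress, rose in 8 of 13 and fell in 0 (9 and 0 adjusted over the list alone; adjusted p 8.75e-09, and 0.0158 with an estimated correlation). Nr1i3, the gene for CAR, fell 1.63-fold (-0.70 ± 0.16).

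Of the G2/M and mitosis genes, 24 of 41 rose and 1 fell (28 and 2 adjusted over the list alone; camera adjusted p 3.53e-15, and 0.0255 with an estimated correlation). Ccnb2, a mitotic cyclin, rose by 5.40 ± 0.29 on the log2 scale, the spindle checkpoint gene Mad2l1 by 4.29 ± 0.34 and the survivin gene Birc5 by 4.57 ± 0.62. Top2a, which untangles chromosomes, rose 7.35-fold (2.88 ± 0.22) and the proliferation marker Mki67 4.85-fold (2.28 ± 0.38). DNA replication genes rose in 18 of 35 and fell in 1 (22 and 2 adjusted over the list alone; adjusted p 4.91e-13, and 0.0255 with an estimated correlation). Among them were the helicase subunit Mcm6 (4.95 ± 0.71, from 51.5 and 20.5 to between 1407 and 1780.0), Rrm2 for nucleotide synthesis (3.43 ± 0.20) and the sliding clamp Pcna (2.39 ± 0.19). G1/S regulators rose in 6 of 20 and fell in 0 (9 and 0 adjusted over the list alone; adjusted p 0.000348, and 0.0577 with an estimated correlation). The cell-cycle transcription factor E2f8 rose by 2.89 ± 0.28. Gadd45b (7.24-fold, 2.86 ± 0.30), Myc (1.59 ± 0.41), Ccnd1 (0.70 ± 0.17) and Ccna2 (1.26 ± 0.28) rose. Foxm1 (0.43 ± 0.24, adjusted p 0.279) and the cell-cycle inhibitor Cdkn1a (0.51 ± 0.21, adjusted p 0.137) did not pass the test. Ribosome biogenesis genes rose in 4 of 22 and fell in 0 (5 and 0 adjusted over the list alone; adjusted p 0.00099, and 0.075 with an estimated correlation). Among them was the nucleolin gene Ncl (0.96 ± 0.16).

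Outside these groups the pancreatic lipase relative Pnliprp1 rose by 5.19 ± 0.41 (from 12.9 and 51.8 to between 1214 and 1891), and the tubulin Tubb6 by 4.98 ± 0.54 (from 21.6 and 17.6 to between 973.6 and 1182). Mical1, an actin regulator, rose by 4.79 ± 0.52, from 8.5 and 7.9, which is under the 16 units, to between 487.6 and 756.2. The purine enzyme gene Adssl1 rose by 4.99 ± 0.17 and the membrane protein Prom1 21.9-fold (4.45 ± 0.39). Rdh16 (-4.51 ± 0.52) and Rdh9 (-3.21 ± 0.25) fell, and so did Acot3 (-4.13 ± 0.63) and Cyp4f14 (-2.75 ± 0.35). Fatty acid oxidation and PPAR alpha target genes fell in 4 of 17 and rose in 0 (6 and 0 adjusted over the list alone; adjusted p 0.0268, and 0.417 with an estimated correlation). Cyp4a14 fell (-3.20 ± 0.36), as did Cpt1a (-1.13 ± 0.15), which carries fatty acids into mitochondria. Of the cholesterol synthesis genes, 8 of 17 fell and 1 rose (11 and 1 adjusted over the list alone; adjusted p 9.83e-06, and 0.237 with an estimated correlation), including Idi1 (-1.21 ± 0.20), Fdft1 (-1.17 ± 0.19) and Hmgcs1 (-1.12 ± 0.19). Gluconeogenesis and glycolysis genes fell in 6 of 13 and rose in 0 (9 and 0 adjusted over the list alone; adjusted p 0.00225, and 0.0594 with an estimated correlation). Among them was the glucose transporter Slc2a2 (-1.87 ± 0.22). Pericentral and Wnt target genes fell in 5 of 14 and rose in 0 (6 and 0 adjusted over the list alone; adjusted p 0.00099, and 0.224 with an estimated correlation), with the glutamate transporter Slc1a2 at -1.62 ± 0.20 and Oat at -1.26 ± 0.18. The periportal genes Etnppl (-2.64 ± 0.15) and Igf1 (-1.42 ± 0.16) fell, in a list with 4 of 12 lower and 1 higher (the same adjusted over the list alone; adjusted p 0.0314, and 0.368 with an estimated correlation).

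Bile acid genes fell in 6 of 18 and rose in 2 (7 and 2 adjusted over the list alone; adjusted p 0.0195, and 0.336 with an estimated correlation). Mitogen ligands and receptors fell in 3 of 21 and rose in 0 (adjusted p 0.0438, and 0.156 with an estimated correlation). Sinusoidal endothelial markers fell in 2 of 15 and rose in 0 (adjusted p 0.0474, and 0.336 with an estimated correlation). Both lists had the same counts adjusted over the list alone. With each array centred on its median the last 2 lists were not called (adjusted p 0.0625 and 0.0576), nor were they when probe sets were averaged (0.0743 and 0.0981). Mitogens were not called with the replicate block (0.0714), nor endothelial markers after quantile (0.0578) or cyclic loess normalization. Periportal genes were not called when probe sets were averaged (0.0519). Single arrays decided 5 calls of WT lists. Fatty acid oxidation was not called without WT day 0 replicate 1 or day 2 replicate 2 (adjusted p up to 0.149), and bile acid genes were not without WT day 2 replicate 2 (0.0878). Periportal genes were not called without WT day 0 replicate 2 or day 2 replicate 2 (adjusted p up to 0.122). Mitogens were not called without WT day 0 replicate 2 or any 1 day 2 replicate (adjusted p up to 0.119). Endothelial markers were not called without WT day 0 replicate 2 or day 2 replicate 1 or 2 (adjusted p up to 0.136).

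In all, limma called 1782 of 14102 genes between WT day 2 and day 0 (Benjamini-Hochberg adjusted p under 0.05), 1024 higher and 758 lower. Over all genes the arrays of the groups did not overlap in 6356 (45.1%), where chance gives 20%. Without WT day 0 replicate 1 the count was 881, and without replicate 2 it was 880. Calls lost without 1 array were those of Myc (0.87, adjusted p 0.232, without WT day 0 replicate 1, and 1.40 without WT day 2 replicate 2), Ccnd1 (0.66 to 0.74 without WT day 0 replicate 1 or 2 or WT day 2 replicate 3, and also without the trend and robust options), Ccna2 (1.10 without WT day 0 replicate 2), Gadd45a (1.41 without WT day 0 replicate 1) and Nr1i3 (-0.45 without WT day 0 replicate 1, and -0.58 and not called with each array centred on its median).

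In KO livers, CAR target, DNA replication and G2/M genes were called higher at day 2 than at day 0, calls that were lost with an estimated correlation (adjusted p 0.0872 to 0.0895). The comparison shows what differed 2 days after TCPOBOP in livers given the Cre virus aimed at hepatocyte Yap1. As in WT, no group without TCPOBOP was sampled after day 0. Cyp2b10 rose 20.8-fold (log2 4.38 ± 0.11), from 1771 and 1867 to signals between 36514 and 40975. Cyp2c55 rose 49.5-fold (5.63 ± 0.17). Cdk1 rose by 3.34 ± 0.27 and Top2a 2.99-fold (1.58 ± 0.22). Igfbp1, a secreted binding protein of insulin-like growth factors, fell 12.8-fold (-3.67 ± 0.35), and G6pc, which releases glucose from the liver, fell 6.47-fold (-2.70 ± 0.30). Both falls began from day 0 levels above those of WT. Igfbp1 read 18268 and 8793 in KO against 1188 and 2555 in WT, and G6pc 16744 and 19908 against 3281 and 2979.

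Of the CAR target and phase I drug metabolism genes, 14 of 26 rose and 2 fell (16 and 2 adjusted over the list alone; camera adjusted p 6.31e-12, and 0.0872 with an estimated correlation). Ces2a rose by 2.81 ± 0.15 on the log2 scale and Cyp3a44 by 2.89 ± 0.30. Set against WT, the deposited rises of abundant genes such as Ces2a may also be shaped by the signal range. Cyp3a11 did not pass the test as deposited (-0.24 ± 0.14, adjusted p 0.332) and was higher after quantile normalization (0.45, adjusted p 0.00334). Phase II conjugation and drug transporter genes rose in 19 of 31 and fell in 2 (23 and 2 adjusted over the list alone; adjusted p 7.3e-15, and 0.00269 with an estimated correlation). Sult1e1 rose by 4.45 ± 0.41, Gstm2 by 2.81 ± 0.17 and Gstm3 by 2.63 ± 0.18. NRF2 target genes rose in 5 of 13 and fell in 1 (the same adjusted over the list alone; adjusted p 0.000742, and 0.0872 with an estimated correlation). Pnliprp1 (4.55 ± 0.41), Adssl1 (4.33 ± 0.17), Prom1 (3.93 ± 0.39) and the acute phase genes Orm3 (4.17 ± 0.19) and Orm2 (3.77 ± 0.29) were among the largest rises. Nr1i3 fell 1.54-fold (-0.63 ± 0.16).

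DNA replication genes rose in 11 of 35 and fell in 0 (14 and 0 adjusted over the list alone; camera adjusted p 1.04e-07, and 0.0872 with an estimated correlation). Among them was the helicase subunit Mcm2 (2.32 ± 0.26). Of the G2/M and mitosis genes, 12 of 41 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p 3.49e-07, and 0.0895 with an estimated correlation). Ccnb2 rose by 3.36 ± 0.29, Mad2l1 by 2.58 ± 0.34 and Mki67 by 1.48 ± 0.38. Myc (5.21-fold, 2.38 ± 0.41), Ccnd1 (2.52-fold, 1.33 ± 0.17), Ccna2 (1.36 ± 0.28) and Gadd45b (8.51-fold, 3.09 ± 0.30) rose. Foxm1 (0.04 ± 0.24, adjusted p 0.954) and Cdkn1a (-0.22 ± 0.21, adjusted p 0.589) did not pass the test. The heat shock gene Hspa1b rose 6.20-fold (2.63 ± 0.30), in a list of immediate early and stress genes with 3 of 16 higher and 0 lower (5 and 0 adjusted over the list alone; adjusted p 0.0128, and 0.125 with an estimated correlation).

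Gluconeogenesis and glycolysis genes fell in 6 of 13 and rose in 0 (9 and 0 adjusted over the list alone; camera adjusted p 3.49e-07, and 0.0193 with an estimated correlation). Fbp1, an enzyme of glucose synthesis, changed by -1.09 ± 0.12 (-0.75 after quantile normalization). Periportal genes fell in 7 of 12 and rose in 0 (8 and 0 adjusted over the list alone; adjusted p 2.31e-08, and 0.0872 with an estimated correlation). Etnppl changed by -2.26 ± 0.15 and Igf1 by -1.82 ± 0.16. Fatty acid oxidation and PPAR alpha target genes fell in 7 of 17 and rose in 1 (11 and 1 adjusted over the list alone; adjusted p 1.48e-06, and 0.159 with an estimated correlation). Cyp4a14 changed by -2.53 ± 0.36 and Ppara by -1.18 ± 0.21. Rdh16 (-3.97 ± 0.52) and Serpina12, the gene of a secreted serine protease inhibitor (-3.82 ± 0.58), were among the largest falls. Hepatocyte identity genes fell in 8 of 18 and rose in 0 (9 and 0 adjusted over the list alone; adjusted p 7.79e-06, 0.174 with an estimated correlation and 0.0588 after quantile normalization), including the plasma protein genes Apoh (-1.04 ± 0.13) and Ahsg (-1.02 ± 0.13), which stood at -0.58 and -0.54 after quantile normalization, both called.

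Cholesterol synthesis genes fell in 5 of 17 and rose in 0 (8 and 0 adjusted over the list alone; adjusted p 1.2e-05, and 0.174 with an estimated correlation). Bile acid genes fell in 6 of 18 and rose in 2 (8 and 2; 0.000447 and 0.159), and pericentral genes fell in 5 of 14 and rose in 0 (6 and 1; 0.00381 and 0.19). Lipogenesis genes fell in 6 of 18 and rose in 1 (10 and 3 adjusted over the list alone; adjusted p 0.00588, 0.297 with an estimated correlation and 0.117 after quantile normalization). Acute phase genes fell in 8 of 23 and rose in 4 (9 and 4; 0.0112, 0.159 and 0.276). G1/S regulators rose in 3 of 20 and fell in 1 (4 and 1; 0.0309, 0.159 and 0.0553). Kupffer cell markers fell in 3 of 17 and rose in 0 (5 and 0 adjusted over the list alone; adjusted p 0.0301, and 0.162 with an estimated correlation). Stellate cell markers fell in 4 of 17 and rose in 0 (5 and 1; 0.0339 and 0.174). Kupffer and stellate cell markers were not called when probe sets were averaged (adjusted p 0.136 and 0.132). Kupffer markers were not called with array weights either, nor stellate markers with only the 5 arrays compared or the replicate block. The last 4 calls rested on single arrays. Without KO day 0 replicate 1 the adjusted p was 0.149 for acute phase genes, 0.149 for G1/S regulators and 0.108 for stellate cell markers. It was 0.084 for G1/S regulators without KO day 2 replicate 2 and 0.0792 for stellate cell markers without KO day 2 replicate 3. For Kupffer cell markers it was 0.0707 without KO day 0 replicate 2 and 0.0898 without KO day 2 replicate 1.

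Limma called 1225 of 14102 genes between KO day 2 and day 0, 592 higher and 633 lower. Over all genes the arrays did not overlap in 5695 (40.4%, against 20% by chance). The count was 801 when only the 5 arrays compared were fitted and 777 without KO day 2 replicate 2. Mki67 lost its call without KO day 0 replicate 1 or any 1 of the KO day 2 replicates (0.77 to 1.57, adjusted p up to 0.205), and Ccna2 without KO day 0 replicate 1 (0.88, adjusted p 0.076). Nr1i3 lost its call without KO day 0 replicate 1 or 2 or KO day 2 replicate 1 or 2 (-0.69 to -0.56). Mki67 and Nr1i3 were not called without the trend and robust options or with array weights, nor Mki67 with only the 5 arrays compared or the replicate block. Top2a (0.41) and Ccna2 (0.90) were not when probe sets were averaged. The 2 responses share no array, but both take each gene's residual variance from the same fit. Fisher's exact test also treats genes as independent, so its p does not measure the spread between animals. Of the genes higher at day 2, 292 were higher in both genotypes, of 1024 in WT and 592 in KO, where independent lists would share 43 (Fisher's exact test, p 1.84e-182). Of the genes lower, 218 were lower in both, of 758 and 633, where 34 would be shared by independent lists (Fisher's exact test, p 1.57e-123). Another 23 genes were higher in WT and lower in KO, and 9 the other way.

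**Figure D2:**
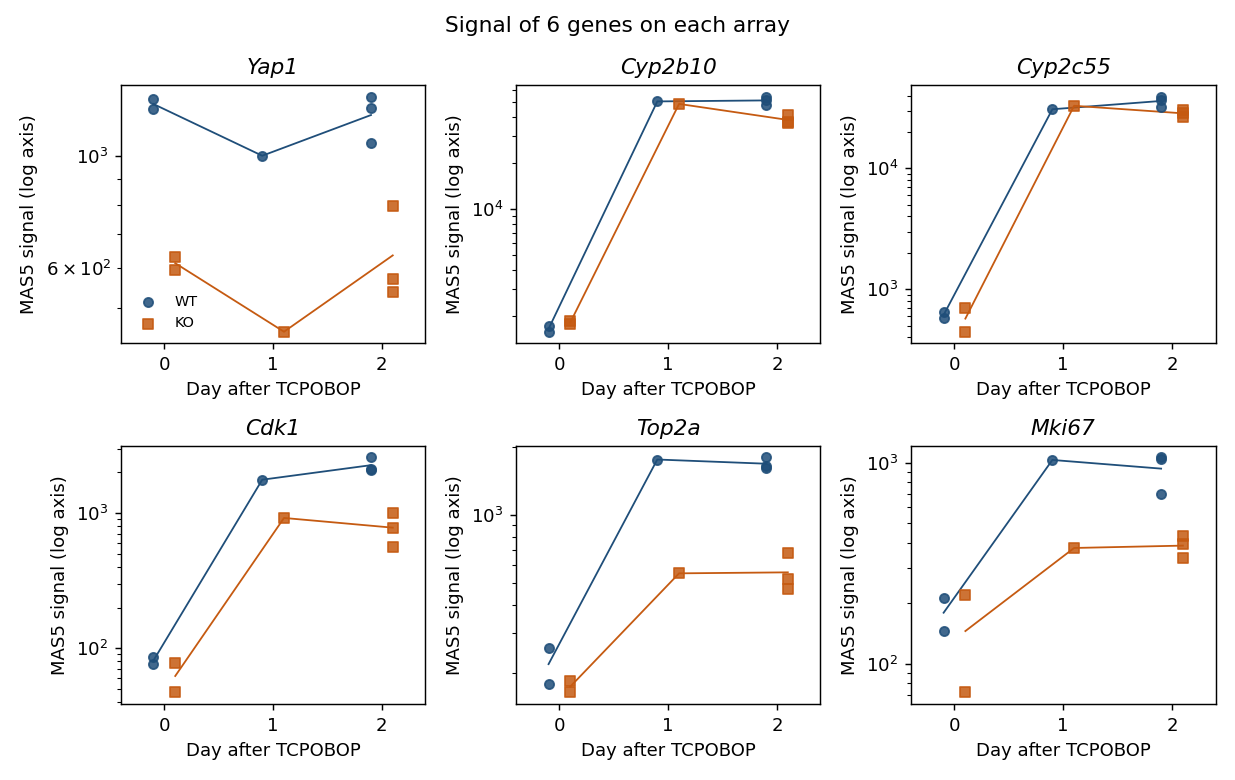
Signal of 6 genes on each of the 12 arrays (vertical axis, MAS5 signal on a log scale) by day after TCPOBOP (horizontal axis), with WT and KO in separate colours and lines joining the group means. Cyp2b10 and Cyp2c55 rise in both genotypes, while Cdk1, Top2a and Mki67 at day 2 lie lower on all 3 KO arrays than on the 3 WT arrays.

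Compared directly at day 2, the lists of genes for mitosis and DNA replication were called lower in KO than in WT livers, and both calls were lost with an estimated correlation (adjusted p 0.0965). This contrast asks what hepatocyte YAP changes once the mitogen has acted. Cdk1 was 2.93-fold lower in KO (log2 -1.55 ± 0.24), with 562.4 to 1004 against 2088 to 2581 in WT. Top2a was 3.00-fold lower (-1.59 ± 0.19), and the checkpoint gene Mad2l1 4.04-fold lower (-2.02 ± 0.31). Cyp2c55 differed by -0.34 ± 0.16 (adjusted p 0.177) as deposited and by 0.19 after quantile normalization (adjusted p 0.455), and passed neither test. The difference of Cyp2b10 was 1.34-fold as deposited (-0.42 ± 0.10, adjusted p 0.0263) but 0.10 with the opposite sign after quantile normalization (adjusted p 0.478).

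Of the G2/M and mitosis genes, 15 of 41 were lower in KO and 0 higher (17 and 5 adjusted over the list alone; camera adjusted p 8.34e-08, and 0.0965 with an estimated correlation). Cdc20, which starts anaphase, was 4.43-fold lower (-2.15 ± 0.23) and the cyclin Ccnf was lower by a log2 of -2.38 ± 0.39. Mki67 was 2.33-fold lower (-1.22 ± 0.34, adjusted p 0.0458). Its call was lost without 8 of the 10 replicate arrays, each left out alone (-1.41 to -1.12, adjusted p up to 0.139), and was kept only without KO day 0 replicate 1 or 2. It was also lost without a pseudocount, without a filter and with the replicate block. DNA replication genes were lower in 8 of 35 and higher in 0 (15 and 1 adjusted over the list alone; adjusted p 1.39e-06, and 0.0965 with an estimated correlation). Among them were Tk1 for thymidine salvage (-1.63 ± 0.19) and Pcna (-1.41 ± 0.17). Ribosome biogenesis genes were lower in 2 of 22 and higher in 0 (10 and 0 adjusted over the list alone; adjusted p 0.00101, and 0.0965 with an estimated correlation). The 2 were Nop56 (-0.81 ± 0.21) and Ncl (-0.59 ± 0.14), and neither was called without the trend and robust options or when probe sets were averaged. Nop56 lost its call without WT day 2 replicate 2 or 3 or KO day 2 replicate 1 or 2 (-0.78 to -0.68, adjusted p up to 0.117). Ncl lost its call without WT day 2 replicate 1 or 2 or KO day 2 replicate 2 or 3 (-0.57 to -0.47, adjusted p up to 0.105), and after quantile normalization (-0.49, adjusted p 0.0632). These 3 lists kept their direction and call after quantile normalization. Ccnd1 (-0.17 ± 0.15), Myc (0.03 ± 0.36), Ccna2 (-0.59 ± 0.25), Gadd45b (0.19 ± 0.27), Foxm1 (-0.42 ± 0.21), Cdkn1a (0.03 ± 0.19) and Nr1i3 (-0.05 ± 0.14) did not pass the test. The 20 measured YAP/TAZ target genes held 0 higher and 0 lower (mean 0.03, adjusted p 0.987, and mean -0.10 after quantile normalization). Its members Ccn1 (-0.33 ± 0.30) and Ccn2 (0.49 ± 0.33) did not pass the test.

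The largest differences were in Tubb6, lower in KO (-4.38 ± 0.48; 33.9 to 40.6 against 973.6 to 1182), and Tnfrsf12a, the receptor of the growth factor TWEAK, 17.2-fold lower (-4.11 ± 0.26; 145.6 to 155.8 against 2386 to 3679.6). Higher in KO were the heat shock gene Hspa1b (8.28-fold, 3.05 ± 0.27), the dynein Dnah5 (4.81-fold, 2.27 ± 0.26), the stress gene Chac1 (2.45-fold, 1.29 ± 0.16) and the transporter Slco1a1 (2.33-fold, 1.22 ± 0.19, but 0.62 and not called when its probe sets were averaged). Slco1a1 already read higher in KO at day 0, before TCPOBOP (5547 and 3832 against 1549.5 and 1882 in WT). On the single day 1 pools Hspa1b read 4846 in WT and 5448 in KO. Whether WT livers had an earlier rise rests on that 1 array and is not settled. Acute phase genes were lower in 9 of 23 and higher in 0 (12 and 1 adjusted over the list alone; adjusted p 2.88e-06, 0.0965 with an estimated correlation and 0.178 after quantile normalization). Mt1 and Mt2, whose products bind metals, were 4.93-fold (-2.30 ± 0.40) and 3.57-fold lower (-1.84 ± 0.25), with -2.21 and -1.72 after quantile normalization.

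Abundant transcripts differed with the scaling. Alb, for serum albumin, stood at -1.15 ± 0.13 as deposited and at -0.23 after quantile normalization (adjusted p 0.0577). Apoa1 stood at -1.05 ± 0.13 as deposited and at -0.13 after quantile normalization. In the same order, the heme carrier Hpx stood at -0.98 ± 0.13 and -0.081, Gstm1 at -1.05 ± 0.11 and -0.21, and Ces2a at -0.92 ± 0.14 and -0.046. Cyp3a11 turned from -0.82 ± 0.12 to 0.065. After quantile normalization none of these 6 was called. Gstm3 was called both ways (-1.26 ± 0.16, and -0.57 after quantile normalization). The CAR target and phase I drug metabolism list, with 2 of 26 higher and 8 lower (5 and 13 adjusted over the list alone), had a mean of -0.17 and an adjusted p of 0.00537 as deposited, and 0.497 with an estimated correlation. After quantile normalization its mean was 0.20, called in the opposite direction (adjusted p 0.0119). Phase II genes, with 1 of 31 higher and 7 lower (the same adjusted over the list alone), went from -0.19 (adjusted p 0.0023, and 0.0965 with an estimated correlation) to 0.071 (adjusted p 0.635). Hepatocyte identity genes, with 0 of 18 higher and 4 lower (1 and 6 adjusted over the list alone), went from -0.22 (adjusted p 0.00431, and 0.509 with an estimated correlation) to 0.13 (adjusted p 0.267). NRF2 target genes, with 0 of 13 higher and 3 lower (the same adjusted over the list alone), went from -0.19 (adjusted p 0.0155, and 0.156 with an estimated correlation) to -0.047 (adjusted p 0.267).

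Limma called 1300 of 14102 genes between KO and WT at day 2, 563 higher in KO and 737 lower. Over all genes the arrays did not overlap in 5100 (36.2%, against 10% by chance). With each array centred on its median the split was 233 higher and 1366 lower. The count was 748 without limma's trend and robust options, and 758, 590, 638, 408 and 559 without WT day 2 replicate 1 or 3 or KO day 2 replicate 1, 2 or 3. Without these options Cyp2b10 and Mki67 were not called. Cyp2b10 also lost its call without WT day 2 replicate 1 or 3 or KO day 2 replicate 1 or 2 (-0.42 to -0.38, adjusted p up to 0.108). So did the CAR list without KO day 2 replicate 1 (-0.13, adjusted p 0.0504) and the NRF2 list without WT day 2 replicate 2 (-0.13, adjusted p 0.0672).

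**Figure D3:**
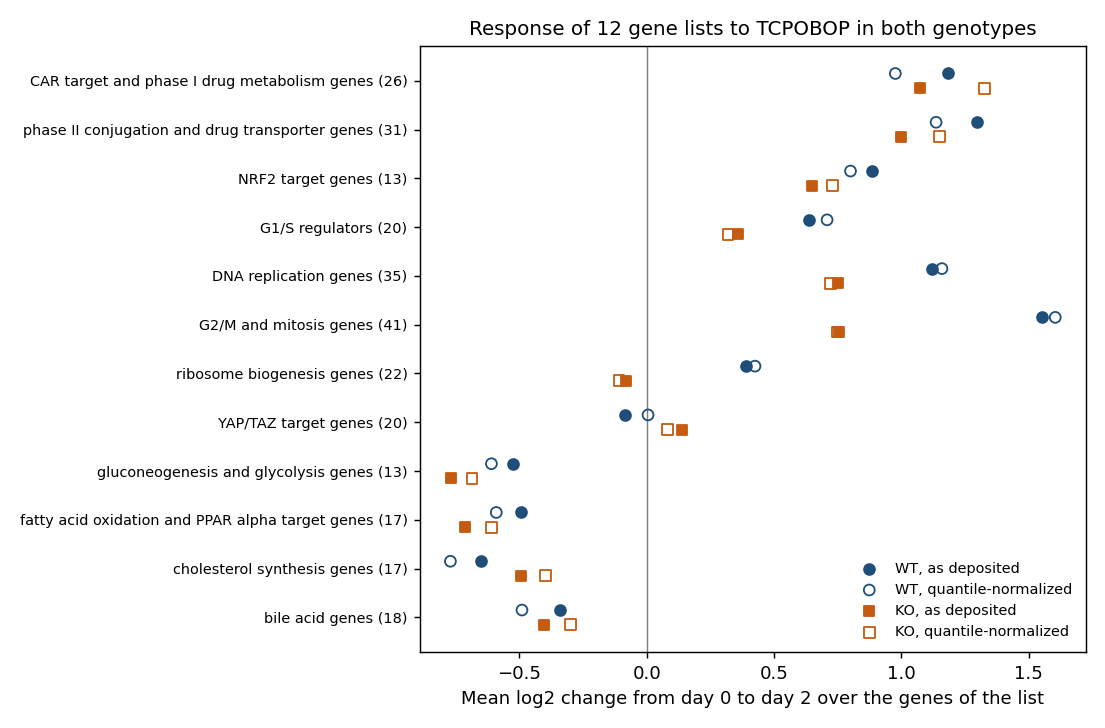
Mean log2 change from day 0 to day 2 (horizontal axis) of the measured genes of 12 lists (vertical axis, number of genes in brackets) in WT and KO, with filled symbols for the deposited values and open symbols after quantile normalization. The G2/M and mitosis list rose by 1.55 in WT and 0.76 in KO as deposited, and for the CAR target list the order of WT and KO turns with the normalization.

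Whether the response itself depended on genotype was tested as the difference between the KO and WT changes from day 0 to day 2. Positive and negative give the sign of the KO change minus the WT change, so a larger fall in KO is negative. For Cdc20 the difference was -2.79 ± 0.36, for the cyclin Ccnf -3.75 ± 0.61 and for the transcription factor E2f8 -2.57 ± 0.40. Levels at day 0 are part of each of these. Cdc20 read 499.1 and 770.5 in KO against 342.7 and 449.1 in WT at day 0. E2f8 read 409.4 and 428.3 in KO against 88.4 and 100.3 in WT at day 0, and 413.6 to 808.5 against 765.1 to 823.4 at day 2. Ccnf read 335.7 and 194.0 in KO against 76.4 and 104.0 in WT at day 0. Tubb6 (-4.45 ± 0.76) and Tnfrsf12a (-3.76 ± 0.41) differed in the same direction. Dbp, an output gene of the circadian clock, moved the other way (3.17 ± 0.42), from a lower level in KO at day 0. The changes of Cyp2b10 (-0.56 ± 0.16, adjusted p 0.0775) and Cyp2c55 (-0.21 ± 0.25, adjusted p 0.655) were not found to differ between the genotypes.

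The G2/M and mitosis list had a mean difference of -0.80 (camera adjusted p 0.000122, and 0.177 with an estimated correlation). Of its genes, 5 of 41 had a negative difference and 0 a positive one (11 and 2 adjusted over the list alone). Top2a was among them (-1.30 ± 0.31, adjusted p 0.0442), a call lost without 8 of the 10 replicate arrays, each left out alone (-1.55 to -1.05, adjusted p up to 0.137), and kept only without KO day 0 replicate 2 or KO day 2 replicate 3. Its call was also lost after quantile normalization (-1.33, adjusted p 0.0507), without a pseudocount, without a filter, when probe sets were averaged, with only the arrays compared, with array weights and with the replicate block. Cdk1 (-1.21 ± 0.37, adjusted p 0.0993) and Mki67 (-0.80 ± 0.54, adjusted p 0.418) did not pass the test. DNA replication genes, with 3 of 35 negative and 2 positive (6 and 2 adjusted over the list alone), had a mean of -0.37 (adjusted p 0.00928, and 0.34 with an estimated correlation). For Pcna the difference was -1.47 ± 0.26. Ribosome biogenesis genes, 3 of 22 negative and 0 positive (7 and 0 adjusted over the list alone), had a mean of -0.47 (adjusted p 0.00325, and 0.177 with an estimated correlation). Ccnd1 (0.63 ± 0.24), Gadd45b (0.23 ± 0.43), Myc (0.79 ± 0.57) and Yap1 (0.11 ± 0.26) did not pass the test as deposited, and Ccnd1 did after quantile normalization (0.94, adjusted p 0.0384).

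Immediate early and stress genes had 2 of 16 positive and 0 negative (4 and 0 adjusted over the list alone). Their mean was 0.69 (camera adjusted p 0.0307, 0.177 with an estimated correlation, 0.0558 after quantile normalization and 0.206 when probe sets were averaged). For Hspa1b the difference was 2.52 ± 0.43, and 1.87 and not called when its probe sets were averaged. For Igfbp1 (-2.80 ± 0.50) the fall in KO began from a higher level at day 0. Abundant transcripts again moved with the scaling: Alb went from -1.54 ± 0.21 to -0.21, Apoa1 from -1.37 ± 0.20 to -0.086 and Cyp3a11 from -1.21 ± 0.19 to 0.007 after quantile normalization, where none of the 3 was called. In the CAR list 1 of 26 genes was positive and 5 were negative (4 and 8 adjusted over the list alone). Its mean was -0.11 as deposited (camera adjusted p 0.0257, and 0.526 with an estimated correlation). After quantile normalization it was 0.35, in the opposite direction (adjusted p 0.0162).

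Limma called 444 of 14102 genes for this difference, 153 positive and 291 negative (KO change minus WT change). With each array centred on its median the split was 75 and 460. The count was 76 without limma's trend and robust options, where Top2a, Pcna, Igfbp1, Hspa1b, Apoa1 and Cyp3a11 were not called, and 288 after quantile normalization. It was 113 and 57 without WT day 0 replicate 1 or 2, 238, 285 and 205 without WT day 2 replicate 1, 2 or 3, 698 without KO day 0 replicate 1, and 230, 89 and 195 without KO day 2 replicate 1, 2 or 3. Without WT day 0 replicate 2 the genes Tubb6 (-4.36), Pcna (-1.31), Hspa1b (2.26), Apoa1 (-1.37) and Cyp3a11 (-1.20) lost their calls. So did Igfbp1 (-2.26) and Cyp3a11 (-1.21) without WT day 0 replicate 1 and Pcna (-1.47) without KO day 2 replicate 2, with adjusted p up to 0.0826. Of the lists, DNA replication lost its call without KO day 0 replicate 2 (-0.30, adjusted p 0.0735), and immediate early genes without WT day 0 replicate 2 or KO day 0 replicate 1 (0.53 and 0.67, adjusted p up to 0.167). CAR targets lost theirs without WT day 0 replicate 1, WT day 2 replicate 1 or 3, KO day 0 replicate 1 or KO day 2 replicate 1 (-0.11 to -0.011, adjusted p up to 0.145).

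Before TCPOBOP, few genes separated the genotypes, a comparison that asks what YAP loss does without the mitogen. Higher in KO were Igfbp1 (7.21-fold, log2 2.85 ± 0.38), G6pc (5.82-fold, 2.54 ± 0.33) and the developmental transcription factor Hhex (2.30-fold, 1.20 ± 0.15). Lower in KO were the clock output genes Dbp (7.19-fold, -2.85 ± 0.33), Nr1d2 (-1.42 ± 0.23) and Tef (-1.22 ± 0.19), the adhesion protein gene Tns2 (-3.08 ± 0.43), Angptl8, a secreted regulator of triglycerides (-1.98 ± 0.23), and Orm3 (-1.74 ± 0.21). Cyp2b10 (0.14 ± 0.12), Cyp2c55 (-0.13 ± 0.19), Cyp3a11 (0.39 ± 0.15), Nr1i3 (-0.13 ± 0.17), Cdk1 (-0.34 ± 0.29), Ccnd1 (-0.80 ± 0.18), Myc (-0.76 ± 0.44), Ccn1 (0.46 ± 0.36) and Ccn2 (0.78 ± 0.40) did not pass the test.

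Circadian clock genes were lower in 3 of 17 and higher in 0 (8 and 0 adjusted over the list alone; camera adjusted p 0.000225, and 0.336 with an estimated correlation), and the list lost its call without KO day 0 replicate 1 (mean -0.34, adjusted p 0.14). Immediate early and stress genes shifted down with 0 of 16 called (1 lower adjusted over the list alone; mean -0.45, adjusted p 0.00902, and 0.327 with an estimated correlation). Periportal genes shifted up with 0 of 12 called (0 adjusted over the list alone; mean 0.29, adjusted p 0.00902, 0.617 with an estimated correlation and 0.171 after quantile normalization). Gluconeogenesis and glycolysis genes, with G6pc as the 1 member of 13 called (1 adjusted over the list alone), had a mean of 0.38 (adjusted p 0.0252, 0.327 with an estimated correlation and 0.235 after quantile normalization). The immediate early list lost its call without WT day 0 replicate 2 or KO day 0 replicate 1. The periportal list lost its call without replicate 1 of either genotype at day 0, and the gluconeogenesis list without WT day 0 replicate 2 or KO day 0 replicate 1 (adjusted p up to 0.202, 0.292 and 0.362). The G2/M and mitosis, DNA replication and CAR target lists were not called (adjusted p 0.907, 0.188 and 0.732). Without KO day 0 replicate 2 the DNA replication list was called (-0.26, adjusted p 0.0419). For G2/M the mean (0.02) and for CAR targets the mean (-0.06) have the sign opposite to the test's.

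Limma called 24 of 14102 genes at day 0, 9 higher in KO and 15 lower. Over all genes the arrays did not overlap in 5015 (35.6%), where chance gives 33.3%. The count was 0 without the trend and robust options and 0 with only the 4 day 0 arrays fitted, beside 1151 genes at an unadjusted p under 0.05. It was 15 and 7 without WT day 0 replicate 1 or 2, 134 and 48 without KO day 0 replicate 1 or 2, and 8 to 15 without any 1 of the 6 day 2 arrays. Of the 9 called genes given above, a subset chosen after the values were seen, Orm3 alone kept its call without each of the 10 replicate arrays. Igfbp1 and Hhex lost it without WT day 0 replicate 1 (2.30 and 1.11), Dbp and Angptl8 without WT day 0 replicate 2 (-2.46 and -1.78), with adjusted p from 0.0647 to 0.091. G6pc lost it without WT day 0 replicate 1 or 2 or KO day 0 replicate 2 (2.42 to 2.61), and Tns2 without these or WT day 2 replicate 2 (-3.09 to -2.86, adjusted p up to 0.164). Tef kept its call only without WT day 2 replicate 1 or KO day 0 replicate 1, and Nr1d2 only without WT day 0 replicate 1 (adjusted p up to 0.247 and 0.175). Both were lost without a filter and when probe sets were averaged. With array weights Igfbp1, G6pc, Tns2, Nr1d2 and Tef were lost, with the replicate block Igfbp1 and Tef, and with cyclic loess normalization Nr1d2.

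At day 1 each genotype has 1 array of pooled RNA, so the values have no replicate check and carry no test. Cyp2b10 read 50355 in WT and 48492 in KO, against day 0 means of 1651 and 1819. Cyp2c55 read 30797 and 32901, Sult1e1 1278 and 1472, and Adssl1 2425 and 3061. The mitosis genes Top2a, with 1756 in WT and 550.3 in KO, Mki67, with 1032 and 376.6, and Cdk1, with 1766 and 920.2, were lower on the KO array. Mcm6 read 1954 and 1079. Ccnd1 read 8056 in WT and 8235 in KO, Myc 662.9 and 807.7, Gadd45b 2770.3 and 2244, Ccna2 870.3 and 947.8, Foxm1 1378 and 1291, Cdkn1a 748.3 and 635.9, Nr1i3 2318 and 2662 and Cyp3a11 74549.9 and 72610.2. The YAP target Ccn1 read 504.2 in WT and 158.1 in KO, and Ccn2 455.4 and 339.6. Rdh16 (49.9 and 52.8, from 921.7 and 1160.2 at day 0), the metallothionein Mt1 (591.3 and 663.2, from 15775 and 8615), Depp1 (252.1 and 507.3), Acsl6 (79.2 and 44.0) and Tmem184a (42.7 and 47.8) were the lowest relative to day 0 in both.

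The G2/M and mitosis list had a median KO minus WT difference of -0.75 at day 1, at percentile 0 of 10000 random lists of the same size and signal. Its median change from day 0 was 1.17 in WT and 0.20 in KO (percentiles 100 and 99.66), the latter 0.35 after quantile normalization. DNA replication genes had a median difference of -0.40 between KO and WT (percentile 0), with changes of 1.35 in WT and 1.00 in KO. For the CAR target and phase I drug metabolism list the median difference was 0.06 (percentile 78.82), with changes from day 0 of 1.05 in WT and 1.03 in KO. The G1/S list differed by 0.002 (percentile 55.81) and the YAP/TAZ target list by -0.27 (percentile 2.34). In both genotypes, 388 genes were at least 2-fold higher at day 1 than at day 0 and 280 at least 2-fold lower.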

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

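The tests chosen only after the result was seen are the correlation of abundant transcripts with the spiked controls, the matched random lists for mitosis genes, the markers of other cell types, the genes of Arntl's phase and the alternatives of lists other than CAR target, DNA replication, G1/S, G2/M and YAP/TAZ target genes.

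Abundant transcripts read lower on the KO day 2 arrays than on the WT day 2 arrays (mean log2 of the 200 most abundant genes, -0.34), and so did the spiked controls (-1.36), which no liver makes. A fall limited to the genes of the hepatocyte lists is argued against: ribosomal protein genes, which every cell expresses, fell more than hepatocyte genes of like signal (median difference -0.37, 95% bootstrap interval -0.74 to -0.24, 34 ribosomal protein and 23 hepatocyte genes). Hepatocytes express ribosomal protein genes too, so this cannot separate the arrays from a change in the hepatocytes. The interval covers genes on the same arrays and does not measure the spread between livers. Within groups, the abundant genes followed the spiked controls over 10 arrays (r = 0.876, exact permutation p 0.0208 of 144 arrangements; Spearman 0.915, exact permutation p 0.0139; r = 0.99 without KO day 2 replicates 2 and 3). A different signal range, by the spiked controls narrower on the KO day 2 arrays and wider on the WT day 2 arrays than at day 0, is therefore a candidate explanation for lower abundant transcripts such as Alb and Apoa1. How much of the fall is due to the liver stays open, since each of the 2 ranges at day 2 belongs to 1 group.

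Mitosis genes were lower in KO at day 2 (list median -0.69), a call lost with an estimated correlation (adjusted p 0.0965). The signal range is argued against as the cause, since 10000 random lists of like signal had medians from -0.02 to 0.33 in their central 95%, all above it, as is a single array, since the median closest to 0 without any 1 day 2 array was -0.61. For endothelial and stellate cells, a fall as large as that of the mitosis genes is argued against by marker medians of 0.236 (SD between 15 genes, 0.54) and 0.187 (SD between 17, 0.555). Of these markers, 2 and 5 were lower in KO. A smaller fall stays open, since the markers were not matched on signal. Genes with mean log2 signals of 8 to 10 had a median of 0.19 in this contrast, and those of 10 to 12 one of -0.06. Fewer macrophages stay open: 8 of their 17 markers were lower in KO, 4 of them called, with a median of 0.139, a mean of -0.17 and an SD of 0.65. What else stays open is loss of YAP in hepatocytes, the hypothesis that the series set out to test, which may act on the size or on the timing of the response, and any difference in handling that the labels do not record. The virus also differs with the genotype (Cre in KO, GFP in WT), and its own effect cannot be told apart from loss of YAP here. For the 1300 genes called between the genotypes at day 2, the 10 splits of the 6 arrays are too few for a share under 0.05; the real split is the 1 with as many genes, and the highest of the others gave 0.

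Clock genes differed between the genotypes at day 0, before TCPOBOP, together with Igfbp1 and G6pc, though the list's adjusted p was 0.336 with an estimated correlation. Other metabolic genes went both ways. Pck1 read 8437 and 16726 in KO against 4935 and 9026 in WT, and Cpt1a 8681 and 6001 against 11505 and 10037. No feeding state is therefore read from Igfbp1 and G6pc. A single array as the cause is argued against: the clock list's median closest to 0 without any 1 day 0 array was -0.39, though its call ended without KO day 0 replicate 1 (mean -0.34, adjusted p 0.14). The contrast planned between clock genes of opposite phase (1.80) decides nothing, since Dbp, Tef and Nr1d2, seen before, are enough to carry it. The 5 genes of Arntl's phase alone had a mean of 0.759 ± 0.24 (SE, n = 2 arrays per genotype), and 0.56 ± 0.26 without Npas2, so a different circadian phase at harvest is a candidate explanation. None of the 5 was called by limma, among them Arntl (-0.08, adjusted p 0.968) and Npas2 (1.57, adjusted p 0.698). Feeding state and an effect of YAP on the clock stay open, since no harvest times are given. So does an effect of the virus itself, Cre in KO and GFP in WT.

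The change from day 0 to day 2 differed between the genotypes, by a test of that difference, for 12 lists. The mean differences were -0.80 for G2/M and mitosis, -0.51 for acute phase, -0.30 for phase II, -0.35 for hepatocyte identity, -0.47 for ribosome biogenesis, -0.37 for DNA replication, -0.33 for periportal, -0.24 for NRF2 target, -0.11 for CAR target, 0.69 for immediate early, -0.32 for p53 target and 0.39 for clock genes. Hepatocyte identity (0.16) and CAR target genes (0.35) turn their sign after quantile normalization, as do phase II genes (0.015). It also ends the calls of acute phase (-0.15, adjusted p 0.945), periportal (-0.099, 0.623), NRF2 target (-0.07, 0.179), immediate early (0.61, 0.0558) and clock genes (0.35, 0.0558). Cyclic loess ends the calls of all these lists but CAR target genes, those of hepatocyte identity and phase II genes included. Averaging probe sets ends those of clock (0.19, 0.206), immediate early (0.50, 0.206), CAR target (-0.075, 0.0609), NRF2 target and periportal genes (-0.18 and -0.24, both 0.058). No filter ends those of clock and CAR target genes, a pseudocount of 64 that of clock genes, and a stricter filter that of p53 target genes (adjusted p 0.0519 to 0.0594). Leaving out 1 array ends some calls. Clock genes lose theirs without WT day 0 replicate 2, WT day 2 replicate 1 or 2, KO day 0 replicate 1 or KO day 2 replicate 3 (0.19 to 0.405, adjusted p up to 0.227). P53 target genes lose theirs without WT day 0 replicate 2, WT day 2 replicate 1 or 3, KO day 0 replicate 1 or KO day 2 replicate 2 (-0.36 to -0.255, adjusted p up to 0.145). Periportal genes lose theirs without WT day 0 replicate 1, WT day 2 replicate 3 or KO day 0 replicate 1 (-0.32 to -0.23, adjusted p up to 0.0801), and hepatocyte identity genes without KO day 0 replicate 1 (-0.16, adjusted p 0.115). DNA replication genes lose theirs without KO day 0 replicate 2 (-0.295, adjusted p 0.0735). Immediate early genes lose theirs without WT day 0 replicate 2 or KO day 0 replicate 1 (0.53 and 0.67, adjusted p up to 0.167). CAR target genes lose theirs without WT day 0 replicate 1, WT day 2 replicate 1 or 3, KO day 0 replicate 1 or KO day 2 replicate 1 (-0.11 to -0.011, adjusted p up to 0.145). All 12 calls are lost with an estimated correlation (adjusted p 0.126 to 0.526).

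The same test called 15 of the genes given in the text, a subset chosen after the values were seen. The differences were -1.54 for Alb, -1.37 for Apoa1, -3.75 for Ccnf, -2.79 for Cdc20, -1.21 for Cyp3a11, 3.17 for Dbp, -2.57 for E2f8, 2.52 for Hspa1b, -2.80 for Igfbp1, 1.59 for Nr1d2, -1.47 for Pcna, 1.43 for Tef, -3.76 for Tnfrsf12a, -1.30 for Top2a and -4.45 for Tubb6. Of these, 6 kept their call without each array: Alb, Ccnf, Cdc20, Dbp, E2f8 and Tnfrsf12a. Nr1d2 lost it without WT day 0 replicate 2 or KO day 2 replicate 2 (adjusted p up to 0.0679), and Tef without WT day 0 replicate 2 (adjusted p 0.0796). Without limma's trend and robust options 8 of the 15 were not called: Top2a, Pcna, Nr1d2, Tef, Igfbp1, Hspa1b, Apoa1 and Cyp3a11. Averaging probe sets ended the calls of Top2a, Nr1d2, Tef and Hspa1b, and quantile normalization those of Top2a, Alb, Apoa1 and Cyp3a11. Cyclic loess ended that of Cyp3a11. Top2a lost its call also without a pseudocount, without a filter, with only the arrays compared, with array weights and with the replicate block.

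The spiked control transcripts, which no comparison uses, were higher on the WT day 2 arrays than on the WT day 0 arrays by 0.63 on the log2 scale. On the KO arrays the same change was -1.04, and at day 0 KO exceeded WT by 0.31.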

How the results depend on the processing

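The tests with cyclic loess normalization, and those of lists other than CAR target, DNA replication, G1/S, G2/M and YAP/TAZ target genes, were chosen only after the result was seen. Of 586 values under alternatives for the results that answer a comparison, 508 stayed the same, 19 lost and 1 gained a call, 54 moved and 4 reversed. A test stayed the same if it kept its side of the threshold. A sign change counted as reversed only where the test was called before or after it. Gene counts stayed the same within a set factor of the main count, and day 1 medians within the SD between replicate arrays. Counts and medians beyond these limits moved. For the genes given in the text and other lists, 5171 of 5491 stayed the same, 293 lost and 14 gained a call, 2 moved and 11 reversed. The G2/M and mitosis list kept its direction and call between the genotypes at day 2 under every scaling, filter, pseudocount and array left out, and lost the call with an estimated correlation. Except where a sentence gives one, the cause was not tested.

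The median of all genes moved with centring from -0.11 to 0.02 in WT day 2 against day 0, from 0.09 to -0.08 between the genotypes at day 2 and from 0.11 to -0.07 for the difference between responses. After quantile normalization the interaction count was 288, and the CAR list turned to 0.20 (adjusted p 0.0119) between the genotypes at day 2 and to 0.35 (adjusted p 0.0162) for the difference. With cyclic loess these were 0.13 (adjusted p 0.102) and 0.32 (adjusted p 0.0205). At day 1 the CAR list median was 0.81 in WT and 0.89 in KO by quantile and 0.745 and 0.88 by cyclic loess, and the G2/M median in KO was 0.35 by quantile. Quantile normalization also reversed Cyp3a11 in KO day 2 against day 0 (0.45), between the genotypes at day 2 (0.065) and in the difference (0.007), Cyp2b10 (0.10) and phase II genes (0.071) at day 2, and hepatocyte identity genes at day 2 (0.13) and in the difference (0.16). Cyclic loess reversed hepatocyte identity (0.085 and 0.075) and phase II genes (0.037 and 0.008) in the same comparisons.

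Without a filter 9 genes were called at day 0 and 275 for the difference, whose CAR shift was -0.065 (adjusted p 0.0594). With a stricter filter the G2/M median at day 1 in WT was 1.00. Averaging probe sets gave a CAR shift of -0.075 in the difference (adjusted p 0.0609) and a G2/M median of 1.55 at day 1 in WT. Without trend and robust the counts were 0 at day 0, 748 at day 2 and 76 for the difference, and 133 genes were lower in both responses. With only the arrays compared they were 0 at day 0 and 801 in KO, and with array weights 4 at day 0. A fold of at least 2, which removes genes by construction, left 717 in WT, 535 in KO and 356 between the genotypes at day 2. An adjusted p under 0.01, stricter by construction, left 0, 861, 568, 272 and 34 (day 0, WT, KO, genotypes at day 2, difference).

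With the replicate number as a replicate block the counts were 8, 1409, 1019, 1137 and 286. Deviations of same-numbered KO and WT arrays from their group means correlated by -0.015 at day 0 and by 0.034, 0.026 and 0.004 at day 2. These values show no sign of pairing but cannot exclude it, since deviations within such small groups mirror each other. The labels do not say that the numbers pair mice.

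With an estimated correlation, which widens the test by construction, the calls that held were phase II, G2/M, DNA replication and NRF2 genes in WT and phase II and gluconeogenesis genes in KO; none held in the other comparisons. Lost were CAR genes in WT (1.18, adjusted p 0.0594), KO (1.07, 0.0872), at day 2 (-0.17, 0.497) and in the difference (-0.11, 0.526); DNA replication genes in KO (0.75, 0.0872), at day 2 (-0.55, 0.0965) and in the difference (-0.37, 0.34); and G2/M genes in KO (0.76, 0.0895), at day 2 (-0.77, 0.0965) and in the difference (-0.80, 0.177).

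Leaving out 1 array gave 7 (WT day 0 replicate 2) to 134 (KO day 0 replicate 1) genes at day 0, 880 (WT day 0 replicate 2) to 2207 in WT, 777 (KO day 2 replicate 2) to 1253 in KO, 408 (KO day 2 replicate 2) to 1828 at day 2 and 57 (WT day 0 replicate 2) to 698 (KO day 0 replicate 1) for the difference. The CAR shift ran from -0.21 to -0.011 in the difference and from -0.21 to -0.13 at day 2, and the DNA replication shift from -0.26 to -0.11 at day 0 and from -0.44 to -0.28 in the difference. Dim genes are limited by background: 3.93% to 5.68% of probe sets on an array read under 16 units.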

Other observations

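The test of CDK inhibitors after quantile normalization was chosen only after the result was seen.

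The acute phase genes Orm2 (log2 2.75 ± 0.29) and Lcn2 (2.11 ± 0.32) rose in WT from day 0 to day 2, while Serpina3n fell in WT (-1.93 ± 0.23) and in KO (-2.45 ± 0.23). Of the unfolded protein response genes, Chac1 (-1.31 ± 0.18) and Herpud1 (-0.93 ± 0.18) fell in WT, and Trib3 (1.07 ± 0.18) and Dnajb9 (1.05 ± 0.16) rose in KO. The interferon-stimulated gene Rsad2 rose in WT (2.13 ± 0.23) and was lower in KO than in WT at day 2 (-1.05 ± 0.20, but -0.60 and not called when its probe sets were averaged), and Oas1a rose in KO (1.95 ± 0.32). Gadd45a, a member of the YAP/TAZ target and CDK inhibitor lists, rose in WT (1.62 ± 0.32, a call lost without WT day 0 replicate 1, where it was 1.41 with an adjusted p of 0.0724) and in KO (3.03 ± 0.32). The complement gene C1qb, made by macrophages, fell in KO (-1.63 ± 0.15). In these values ± is the standard error from limma, with 2 arrays at day 0 and 3 at day 2.

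Several lists were called in no tested comparison. Between the genotypes at day 2 their mean differences and adjusted p were -0.35 and 0.0562 for CDK inhibitors (called after quantile normalization, at -0.41 and 0.0486), -0.13 and 0.463 for Hippo components, 0.21 and 0.169 for interferon-stimulated genes, 0.16 and 0.416 for unfolded protein response genes, -0.14 and 0.736 for cholangiocyte markers, 0.41 and 0.123 for lymphocyte markers, 0.12 and 0.401 for neutrophil markers and -0.55 and 0.462 for the 3 measured erythroid markers. G1/S regulators were not called in that comparison (-0.27, adjusted p 0.0903) and were after quantile normalization (-0.37, adjusted p 0.0383).

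Some lists had a mean and a median of opposite sign. Between the genotypes at day 2 these were clock genes (-0.14 and 0.16) and Kupffer cell markers (-0.17 and 0.14), and in KO from day 0 to day 2 Hippo components (-0.25 and 0.01), mitogens (-0.29 and 0.04) and YAP/TAZ target genes (0.14 and -0.01). For each the test had the sign of the mean.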
